A study of Mus musculus with 6 samples.

How the data were processed

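The series holds 6 RNA sequencing libraries from Min6, a mouse insulinoma line that secretes insulin in response to glucose. All cells had been exposed to 25 mM glucose and 500 µM palmitic acid for 30 h at passage 31, a treatment the labels call glucolipotoxicity. In RNA immunoprecipitation sequencing, RNA that comes down with an antibody against an RNA-binding protein is sequenced beside the RNA of the lysate. Per the labels' protocols, cells were lysed in a buffer with NP-40 detergent, and total RNA was taken from a 10% input of the lysate with a column kit. Lysate holding 200 µg of protein was incubated overnight on beads carrying an antibody against hnRNPK, and the beads were washed with a buffer of higher salt. RNA from the beads was then purified on the same kind of column with a DNase step. Per the labels, libraries followed standard Illumina protocols. Whether ribosomal RNA was removed or polyadenylated RNA selected is not given in the sources used here. An immunoprecipitation with a control antibody was not analysed here, so RNA that sticks to beads or antibody without hnRNPK is counted with the bound RNA.

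The authors' files hold whole-number counts of reads per gene, one table per library, with no normalization. Per the submitters' processing notes, the authors aligned reads to the mm10 genome with TopHat2 and counted them with featureCounts. Per the file headers, each table came from the accepted alignments of a pair of input data sets. The versions, the annotation release, the strand setting and the treatment of reads with several alignments are not given in the sources used here. Each deposited table has 53379 genes. Of these, 53274 had a gene identifier in GENCODE release M21 of the same build, GRCm38, which supplied symbols, coordinates, gene classes and transcript sequences. The 105 others held at most 0.0237% of a library's counts. No entry lacked a gene name. Among counts of 1 to 20, 58.6% to 68.7% were even in each library, a pattern that would arise if both mates of a pair were counted. Halved counts were therefore tried as an alternative. With featureCounts, reads shared by near-identical genes may be dropped or given to 1 copy, which affects ribosomal protein genes and their pseudogenes, histones and mitochondrial genes with nuclear copies. Without a known strand setting, reads of overlapping and antisense genes cannot be told apart.

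Groups were taken from the sample titles, 3 libraries of hnRNPK immunoprecipitated RNA and 3 of total RNA. Total counts ranged from 38764925 to 52735957 per library. No pair of libraries within a group agreed within sampling noise, since chi-square divided by its degrees of freedom was 6.44 to 129 over the 6 such pairs. No label says that the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Counts were tested in R 4.3.3 with edgeR 4.0.16, using TMM factors, filterByExpr (minimum count 10, minimum total count 15) and the quasi-likelihood F test (glmQLFit and glmQLFTest) on the group alone. Fold changes used the default prior count of the fit, and log2 CPM used a prior count of 2. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called enriched or depleted. Normalised counts are given as CPM, with the TMM factors applied, and as mean ± SD of 3 libraries. Log2 fold changes are given as hnRNPK IP minus total RNA, ± SE.

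The groups, tests, alternatives, 21 gene lists and the rule for named genes were chosen before the data were examined. The rule took 7 genes in any case (Hnrnpk, Jund, Ddx3x, Ins1, Ins2, Pdx1 and Myc). It added the 10 highest and 10 lowest log2 fold changes among called genes with at least 5 CPM on average, no overlap between the groups and an established symbol. From each list it took up to 2 members with the highest and 2 with the lowest log2 fold change. Some genes the rule took are not reported here. The lists cover beta cell identity, secretory granules, AP-1 and immediate early factors, endoplasmic reticulum stress, antioxidant genes, apoptosis, cytosolic ribosomal proteins, mitochondrially encoded genes, nuclear oxidative phosphorylation subunits, hnRNP proteins, splicing factors, translation factors, Zfp genes, replication-dependent histones, long noncoding RNAs, matrix and adhesion genes, kinases, mRNAs described earlier as hnRNPK targets, and markers of other islet cells, of exocrine and duct cells, and of stromal, endothelial and immune cells. Each list was compared with all other tested genes by camera from limma 3.58.1 with a preset correlation of 0.01, adjusted over the 21 lists. The list tests were repeated with an estimated correlation and with fry, which asks only whether a list's genes move one way on balance.

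Tetramer densities per kb were computed from the longest annotated 3' UTR, the coding sequence and the 5' UTR of each gene, with at least 100 nt of 3' UTR and 50 nt of the other regions. Spearman correlations with the log2 fold change were tested with 100000 permutations over genes in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Intervals of medians and correlations are 95% percentile intervals from 1000 bootstrap draws over genes. For genes with 1 to 3 reads in the IP group, the ratio of summed reads is given, scaled by library totals and TMM factors, with an exact (Clopper-Pearson) 95% interval, and for genes with none the bound rests on a floor of 3 counts over the group. Such intervals and floors cover counting error only. Alternatives were leaving out each library, RLE and upper-quartile factors, library totals alone, no filter, a filter of 1 CPM in 3 libraries, an adjusted p under 0.01, a test against a 1.5-fold change, mitochondrial genes left out, DESeq2 1.42.0, limma-voom, the replicate number as a block, an offset for exon length (loess span 0.3), and the last pair together. Counts were simulated for the comparison of hnRNPK IP with total RNA over 16487 genes. On these, edgeR recovered 48 of 100 genes changed 2-fold and 69 of 100 changed 4-fold, and called 7 unchanged genes. That simulation changed 200 genes, as many up as down, whereas 10572 of the measured genes were called. Its recovery and false calls therefore do not carry over to the measured comparison. On simulated lists over 16490 genes, 1 of 1 shifted lists and 0 of 20 others were called by camera. Simulated genes varied independently, whereas members of the measured lists had estimated correlations of up to 0.600. The simulation therefore does not give camera's error rate on the measured lists. On simulated fold changes over 12979 genes, 3 of 3 planted tetramers ranked first.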

Results

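RNA recovered with an antibody against hnRNPK was profiled in glucolipotoxic Min6 cells and set against the total RNA of the lysate. hnRNPK is a heterogeneous nuclear ribonucleoprotein whose KH domains bind C-rich single-stranded RNA. The comparison asks which transcripts were over- or under-represented in the IP. The mRNAs of the AP-1 factor Jund and the helicase Ddx3x were among those of interest to the study. IP libraries 1, 2 and 3 held 39290750, 38764925 and 46222181 counts, and total RNA libraries 1, 2 and 3 held 52735957, 46657732 and 46185284. IP libraries detected fewer genes, 19087 ± 1987 against 22350 ± 472 (SD, n = 3 each). Among the 2740 genes with a mean of 10 to 40 counts in total RNA, IP libraries 1, 2 and 3 lacked any read for 828, 1136 and 291, while each total RNA library, on whose means this set rests, lacked 6 to 15. The biological coefficient of variation was 42.6% among IP libraries and 12.2% among total RNA libraries. Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.927 to 0.960 between IP libraries, 0.986 to 0.992 between total RNA libraries and 0.812 to 0.892 between the groups.

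Most of the measured transcriptome differed between IP and total RNA. Without a control antibody, binding to hnRNPK is not separated here from binding to beads or from other effects of the IP protocol. Polr2a, which encodes the largest subunit of RNA polymerase II, the growth factor Igf2 and the synaptic vesicle protein Syn1 were each more than 8-fold higher in the IP. mRNAs for ribosomal proteins and for nuclear subunits of oxidative phosphorylation lay at the depleted end, with Rps14 36.0-fold lower in the IP. Of 16929 genes tested, 4892 (28.9%) were enriched in the IP, 5680 (33.6%) were depleted and 6357 did not pass. At least 2-fold differences were called for 3315 enriched and 4148 depleted genes. In 12095 genes (71.4%) the groups did not overlap, against 10% by chance for 3 libraries against 3. Enrichment is relative, since no RNA of known amount links the groups. With TMM factors 46.3% of calls were enriched, and with library totals alone 32.1%, as the median of all genes shifted by −0.43 on the log2 scale. Reads of mitochondrially encoded genes made up 4.42 ± 1.41% of IP and 1.68 ± 0.258% of total RNA counts, and cytosolic ribosomal protein genes 0.0515 ± 0.0141% and 0.834 ± 0.125% (SD, n = 3 each).

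Among the 7 genes chosen in any case, Pdx1, Jund and Ddx3x were enriched, Hnrnpk, Ins1 and Ins2 were depleted and Myc did not pass. Pdx1, a homeobox factor needed for beta cell function (ENSMUSG00000029644.7, chromosome 5, 147269959 to 147275848), had 925 ± 26.2 CPM in the IP and 323 ± 9.76 in total RNA (SD, n = 3 each). Its log2 fold change was 1.52 ± 0.07 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.34e-06). Jund, an AP-1 subunit encoded by a single exon (ENSMUSG00000071076.6, chromosome 8, 70698949 to 70700616), had 115 ± 2.32 against 67.6 ± 3.22 CPM, 1.70-fold higher in the IP (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.000103). Its log2 fold change of 0.77 ± 0.08 kept its call throughout, between 0.33 with library totals alone and 1.42 with the offset for gene length. Ddx3x, a DEAD-box RNA helicase (ENSMUSG00000000787.12, chromosome X, 13280970 to 13294052), had 592 ± 9.39 against 427 ± 25.6 CPM and a log2 fold change of 0.47 ± 0.08 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.000945). That call ended with library totals alone, at 0.04, and with the offset for gene length, at 0.14 (edgeR quasi-likelihood tests with Benjamini-Hochberg adjusted p = 0.728 and 0.104, range over the alternatives 2.08e-09 to 0.728). Hnrnpk itself had 141 ± 17.7 against 188 ± 9.56 CPM, and its log2 fold change of −0.42 ± 0.11 lost its call without total RNA replicate 2 (−0.35) or 3 (−0.37).

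The insulin mRNAs were less abundant in IP than in total RNA. Ins2 had 1953 ± 524 CPM in the IP and 10471 ± 2728 in total RNA (SD, n = 3 each), a log2 fold change of −2.42 ± 0.25 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 7.99e-05) that was −1.66 with the offset for gene length. Ins1 had 180 ± 43.5 against 379 ± 101 CPM and a log2 fold change of −1.08 ± 0.24, which the offset for gene length took to −0.25, ending the call. Both insulin genes encode near-identical short mRNAs, so the division of reads between them is uncertain. Myc had 5.56 ± 0.450 CPM in the IP and 5.90 ± 0.546 in total RNA (log2 fold change −0.09 ± 0.20).

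**Figure D1:**
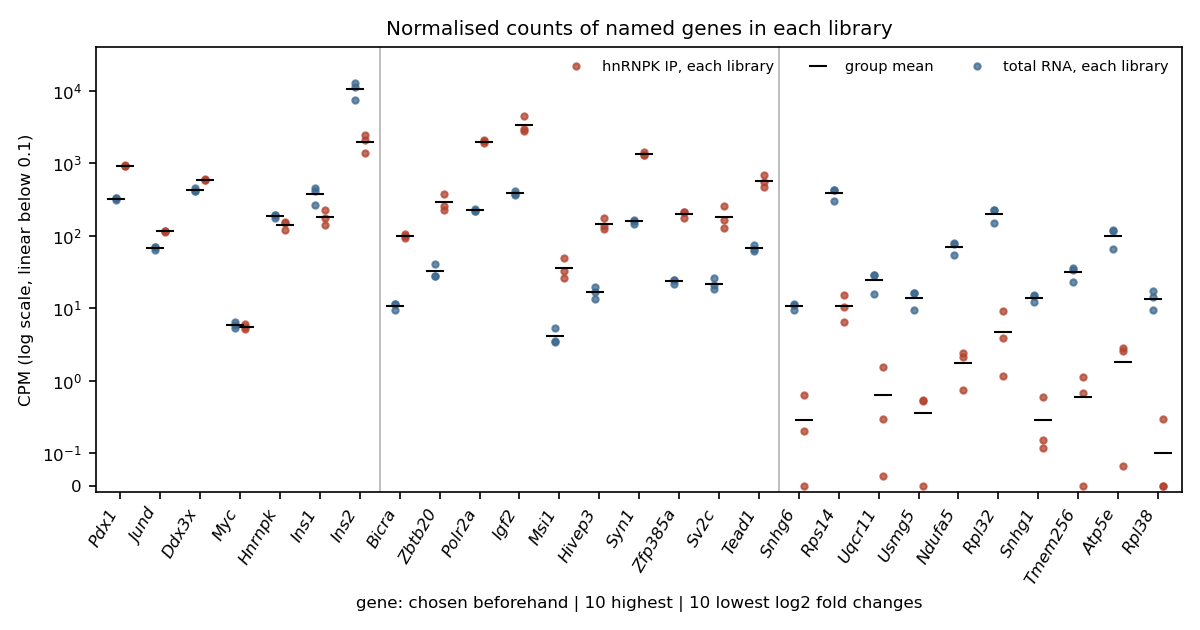
CPM (log scale, linear below 0.1) of the 7 genes chosen in any case and of the 10 highest and 10 lowest log2 fold changes, with a point per library (hnRNPK IP in red, total RNA in blue, n = 3 each) and a bar at each group mean. Polr2a lies at 1992 CPM in the IP against 223 in total RNA, and Rps14 at 10.7 against 385.

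The 10 highest log2 fold changes under the rule were 3.07 to 3.20. They belonged to Bicra, a subunit of a chromatin remodelling complex, the transcription factors Zbtb20, Hivep3 and Tead1, and Polr2a. The others were Igf2, the RNA-binding proteins Msi1 and Zfp385a, and the synaptic vesicle proteins Syn1 and Sv2c. Polr2a had 1992 ± 104 CPM in the IP and 223 ± 8.66 in total RNA (SD, n = 3 each), 8.91-fold higher (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.24e-06). Igf2 had 3412 ± 926 against 385 ± 26.2 CPM, and Syn1 1342 ± 60.8 against 158 ± 10.7. The 10 lowest log2 fold changes were −6.93 to −5.16 and belonged to Rpl38, Rpl32 and Rps14 of the ribosome, Atp5e, Ndufa5, Usmg5 and Uqcr11 of oxidative phosphorylation, Tmem256, and the snoRNA host transcripts Snhg1 and Snhg6. Rps14 had 10.7 ± 4.39 CPM in the IP against 385 ± 73.2 in total RNA (log2 fold change −5.17 ± 0.33). Rpl38 rests on 12 reads in the IP group, all of them in IP library 3, against 2267 in total RNA. Its log2 fold change ranged from −12.3 to −6.02 over the alternatives. These 20 genes kept direction and call in every alternative that tested them.

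Cytosolic ribosomal protein mRNAs were depleted almost throughout. Of 87 measured members, 2 were enriched and 80 depleted over all genes tested (2 and 82 adjusted over the list alone), and the median log2 fold change was −4.08. Camera placed the list below the other genes (Benjamini-Hochberg adjusted p = 4.85e-14; adjusted p = 0.658 with an estimated correlation). The enriched members were Rpl28, at 0.84 ± 0.26, and Rps4l, a transcribed processed pseudogene with 1.95 ± 1.86 CPM in the IP, at 3.16 ± 0.82. Rpl28 lost its call in 5 of 6 leave-one-out fits, all but that without IP replicate 2, with values of 0.51 to 0.92, and with library totals alone, at 0.41. Rpl30 had 0 reads in the IP group and 199 in total RNA, at least 41.9-fold lower with TMM factors. With Rpl30 at its bound the list's median stayed at −4.08. Ribosomal protein genes share sequence with many pseudogenes, so single values depend on how shared reads were assigned. Nuclear subunits of oxidative phosphorylation had 0 enriched and 73 depleted of 80 members (0 and 73 adjusted over the list alone), with a median of −3.40. The count of 0 by edgeR was also 0 at an unadjusted p under 0.05, and 0 with DESeq2 and limma-voom. Camera gave a Benjamini-Hochberg adjusted p = 5.38e-15 (adjusted p = 0.658 with an estimated correlation). Ndufb2 at 0.43 ± 0.21 and Atp5g2 at 0.03 ± 0.59 had the highest values of this list and did not pass, although Ndufb2 was called without IP replicate 2, at 0.58.

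Antioxidant genes went both ways, with 6 enriched and 19 depleted of 30 (6 and 20 adjusted over the list alone) and a median of −1.38. Gpx3, a secreted glutathione peroxidase, was enriched (2.25 ± 0.20), as was mitochondrial Sod2 (1.46 ± 0.13), while Prdx5 (−4.11 ± 0.62) and the cytosolic dismutase Sod1 (−4.22 ± 0.22) were depleted. Camera called this list lower (Benjamini-Hochberg adjusted p = 0.0280; adjusted p = 0.658 with an estimated correlation), and the offset for gene length ended the call (adjusted p = 0.0952, range over the alternatives 0.00774 to 0.658). Of 30 kinase and signalling genes, 18 were enriched and 6 depleted (the same counts adjusted over the list alone), with a median of 0.62. The catalytic subunit of protein kinase A, Prkaca (2.82 ± 0.13), and Gsk3a (2.52 ± 0.12) were highest, and Map2k2 (−1.63 ± 0.13) and Cdk5 (−1.73 ± 0.25) lowest. Matrix and adhesion genes had 14 enriched and 4 depleted of 31 (the same adjusted over the list alone) and a median of 0.67. Highest were Igf1r, a growth factor receptor that this list includes, at 1.86 ± 0.16 and the dystroglycan gene Dag1 at 1.81 ± 0.07. Agrn at −0.68 ± 0.13 and Itgb5 at −1.39 ± 0.09 were lowest. Camera placed both lists above the other genes, with Benjamini-Hochberg adjusted p = 0.00688 for kinases (adjusted p = 0.422 with an estimated correlation) and 0.0249 for matrix genes (adjusted p = 0.658 with an estimated correlation). With the offset for gene length the kinase list had 16 enriched and 11 depleted members and a median of 0.41, and its call ended (adjusted p = 0.281, range over the alternatives 0.000504 to 0.422), and the matrix list had 8 enriched and 11 depleted and a median of −0.11 (adjusted p = 0.0952, range 0.00351 to 0.658).

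Genes of the beta cell went both ways. Of 28 beta cell identity genes, 15 were enriched and 9 depleted, with a median of 0.31. Library totals alone gave 9 and 12 with a median of −0.13, and without IP replicate 3 the counts were 10 and 9. The fatty acid receptor Ffar1 (2.00 ± 0.12) and the homeobox factor Nkx2-2 (1.93 ± 0.08) were highest, and the amyloid polypeptide Iapp was lowest, at 1461 ± 23.0 CPM in the IP and 14161 ± 2378 in total RNA (SD, n = 3 each). Secretory granule genes had 12 enriched and 8 depleted of 24 (median 0.45). Syt7 (2.67 ± 0.10) and Vamp2 (2.65 ± 0.13), which act in vesicle fusion, were enriched, and the carboxypeptidase Cpe (−2.04 ± 0.17) and the chaperone Scg5 (−3.13 ± 0.19) of hormone processing were depleted. Among 31 AP-1 and immediate early genes, 13 were enriched and 10 depleted, with a median of 0.43 that library totals alone took to −0.01. Fosb (2.72 ± 0.14) and Egr1 (2.64 ± 0.12) led, and Junb (−1.98 ± 0.19) and Ier3 (−2.75 ± 0.33) were lowest. Endoplasmic reticulum stress genes had 9 enriched and 17 depleted of 29 (median −0.89), from the ubiquitin ligase Syvn1 (2.29 ± 0.10) and the stress sensor Atf6 (1.49 ± 0.10) to Sdf2l1 (−2.80 ± 0.21) and Selenos (−3.24 ± 0.15). Of 30 apoptosis regulators 10 were enriched and 8 depleted (median 0.04, mean −0.12, and 8 and 13 with a median of −0.39 with library totals alone). The death receptor Tnfrsf10b (2.85 ± 0.33) and the pore-forming protein Bak1 (2.52 ± 0.12) were enriched and its relative Bax (−2.80 ± 0.27) was depleted. Casp6 (−2.98 ± 0.92) lost its call without any 1 of the total RNA libraries, at −2.98 to −2.91. Counts adjusted over the list alone were the same for these 5 lists, and camera called none of them, with Benjamini-Hochberg adjusted p of 0.317, 0.218, 0.405, 0.276 and 0.772 in this order.

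Genes for RNA-binding proteins also divided. Of 32 hnRNP genes, 10 were enriched and 18 depleted (median −0.58), with the poly(C)-binding protein Pcbp2 (2.25 ± 0.08) and Ptbp3 (2.02 ± 0.17) against Hnrnph3 (−2.43 ± 0.20) and Hnrnpa1 (−2.45 ± 0.12). Splicing factors had 6 enriched and 18 depleted of 32 (median −0.67). Sf3a2 was enriched at 2.89 ± 0.16, Snrpe (−4.17 ± 0.63) and Snrpd2 (−4.46 ± 0.41) were depleted, and Snrpf at 1.55 ± 0.96 did not pass. Translation factors had 11 enriched and 18 depleted of 33 (median −0.80), from Eif4ebp2, which restrains cap-dependent initiation (2.64 ± 0.10), and Ddx6 (2.23 ± 0.26) to Eif3h (−3.03 ± 0.26) and Eif3g (−3.17 ± 0.12). Of 339 Zfp genes, 92 were enriched and 95 depleted (91 and 92 adjusted over the list alone), among them Zfp609 (2.89 ± 0.12), Zfp472 (−2.55 ± 0.44) and Zfp330 (−3.02 ± 0.19). Library totals alone gave 57 and 150, and the offset for gene length 71 and 120. Their median was −0.12 although camera placed the list upward. Of 44 histone genes 4 were enriched and 5 depleted (2 and 5 adjusted over the list alone), including Hist2h2be (1.97 ± 0.17), Hist1h2be (1.75 ± 0.41), Hist1h2bc (−3.04 ± 0.25) and Hist1h4h (−4.67 ± 1.12). All 14 IP reads of Hist1h4h lay in IP library 3, and its value ranged from −10.3 to −3.79 over the alternatives. Depleted histone genes numbered 10, 12 and 8 without IP replicate 1, 2 and 3, enriched ones 2 without any 1 of the total RNA libraries, and the offset for gene length gave 8 enriched and 4 depleted. Their median of 0.004 and mean of −0.47 differed in sign, and camera pointed down. Over all alternatives that median went from −1.02 to 0.73. Long noncoding RNAs had 7 enriched and 12 depleted of 28 (median −0.32). Meg3 (2.43 ± 0.11) and Peg13 (2.32 ± 0.10), both imprinted, were enriched, and Epb41l4aos had 1 IP read against 466, a ratio of 294-fold lower with TMM factors and a counting interval of 52.6 to 11652. Except where given, counts adjusted over the list alone were the same. Camera called none of these 6 lists, with Benjamini-Hochberg adjusted p of 0.216, 0.0790, 0.405, 0.827, 0.609 and 0.652 in this order. With the offset for gene length camera called splicing and translation factors lower, with medians of −1.39 and −0.78, and histones higher, with a median of 0.73. Without the offset, these lists had adjusted p = 0.658, 0.675 and 0.675 with an estimated correlation, which was not run with it. That offset left 5 enriched hnRNP genes, 7 translation factors and 4 long noncoding RNAs, and library totals alone 6 hnRNP genes.

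mRNAs described earlier as hnRNPK targets had 5 enriched and 3 depleted of 11. Their median of 0.77 is the value of Jund, itself a member, so it is not independent of the result for Jund. Ucp2, a mitochondrial carrier, was enriched (2.65 ± 0.16), as was the cell cycle inhibitor Cdkn1a (2.15 ± 0.15), while Gap43 (−1.25 ± 0.17) and Mdm2 (−1.27 ± 0.11) were depleted. Of 12 mitochondrially encoded protein genes 7 were enriched and 0 depleted by edgeR (0 at an unadjusted p under 0.05, and 0 with DESeq2 and limma-voom), with a median of 1.53. mt-Nd6 (2.77 ± 0.24) and mt-Nd5 (2.74 ± 0.21), which overlap on opposite strands, were highest, and mt-Co3 (−0.47 ± 0.62) and mt-Nd4l (−0.94 ± 1.08), with few reads, did not pass. Markers of other islet endocrine cells had 1 enriched and 5 depleted of 11 (median −0.71), with 3, 2 and 2 depleted without total RNA replicate 1, 2 and 3. The offset for gene length gave 2 enriched and 3 depleted with a median of −0.25, and camera then pointed upward without a call. Etv1 was enriched (1.91 ± 0.10) and the transthyretin gene Ttr (−2.21 ± 0.21) was depleted. Ppy (−3.75 ± 1.25) lost its call without any 1 of the total RNA libraries, at −3.97 to −3.57, and with the offset for gene length, at −2.89. All 18 IP reads of Ppy lay in IP library 3, and over all alternatives its value ranged from −9.68 to −2.89. Exocrine and duct markers had 3 enriched and 3 depleted of 7 (median 0.47, but −0.53 without IP replicate 2 and −0.53 to 1.01 over all alternatives), with Muc1 (1.85 ± 0.39) against Krt7 (−1.76 ± 0.18) and Spp1 (−2.47 ± 0.23). Camera placed this list upward and fry downward. Stromal, endothelial and immune markers had 5 enriched and 0 depleted of 9 by edgeR (median 1.85), at low levels, with 0 depleted also at an unadjusted p under 0.05 and with DESeq2 and limma-voom. The 1 CPM filter left 2 enriched of 5 measured, the offset for gene length with the block 2 of 9, and halved counts, chosen after seeing the data, 3 of 6. Col3a1 had 0.903 ± 0.217 CPM in the IP and 0.0827 ± 0.0275 in total RNA and Cd79a 0.977 ± 0.632 and 0.101 ± 0.00933, whereas Cd68 (0.42 ± 0.52) and Vim (−0.29 ± 0.51) did not pass. With 14 and 17 reads in total RNA, Col3a1 and Cd79a entered the test only through their IP counts. The filter fixed the direction of such members, so they add no evidence to the list's count, median or camera result. Counts adjusted over the list alone were the same for these 5 lists, and camera called none, with Benjamini-Hochberg adjusted p of 0.436, 0.0702, 0.553, 0.868 and 0.0596 in this order. The mitochondrially encoded and the stromal lists were called by camera without IP replicate 2, with medians of 1.86 and 1.17 (Benjamini-Hochberg adjusted p = 0.0293 for each). Without total RNA replicate 2 their medians were 1.86 and 1.70 (adjusted p = 0.0478 and 0.0475). Over all alternatives their adjusted p ranged from 1.84e-05 to 0.675 and from 0.0242 to 0.658, and several other settings also called them.

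**Figure D2:**
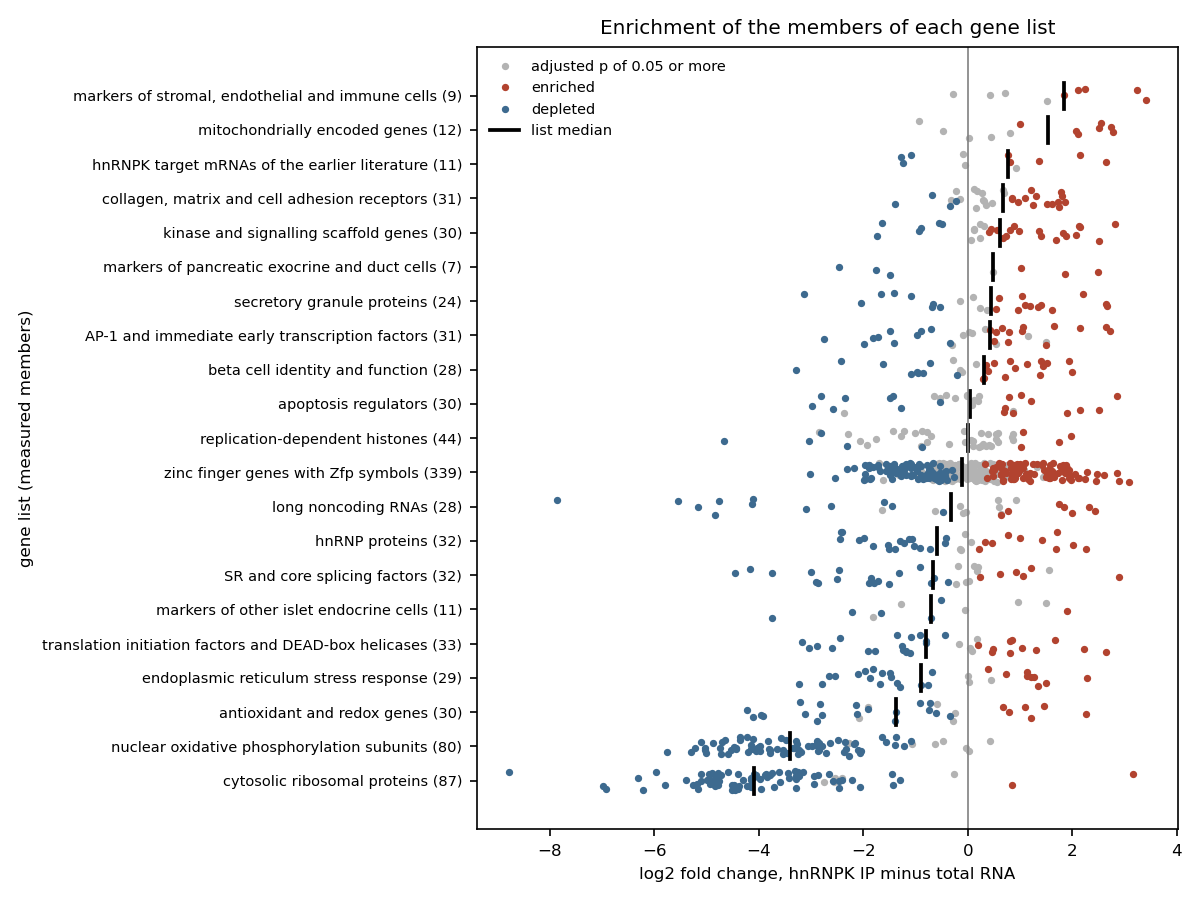
Log2 fold change (hnRNPK IP minus total RNA) of each measured member of the 21 gene lists, with enriched genes in red, depleted genes in blue, genes that did not pass in grey and a black bar at the list median. Ribosomal protein genes (median −4.08) and oxidative phosphorylation subunits (−3.40) lie lowest, and with library totals alone the medians of beta cell, AP-1 and apoptosis genes fall below 0 (−0.13, −0.01 and −0.39).

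The C-rich sequence that hnRNPK's KH domains bind was counted in the mRNAs. Across 12979 protein-coding genes, which are not independent replicates, log2 fold change was correlated with the density of TCCC in the 3' UTR (Spearman's rho 0.27, 95% interval 0.25 to 0.282; 2-sided permutation test p = 1e-05, the smallest that 100000 permutations can give). Among all possible tetramers TCCC ranked 2 in the 3' UTR, after CCCC (0.31) and before CCCA (0.23), ACCC (0.22) and CCCT (0.22). CTCC and CCTC, which like CCCT hold the bases of TCCC in another order, gave 0.21 and 0.19 and ranked 7 and 12. They are C-rich themselves and so no negative controls, and these values do not set TCCC apart from C-rich sequence in general. TAAA had the lowest value, −0.18. Correlations were computed for every possible tetramer in each of 3 regions. In the coding sequence TCCC reached 0.20 and CCCC 0.24, and in the 5' UTR of 11274 genes 0.08 and 0.14. Given GC content and length of the 3' UTR, the partial correlation was 0.25 for TCCC and 0.29 for CCCC. That of TAAA was then −0.03, and GCTG had the lowest, −0.15. Each IP library set against the mean of total RNA gave a TCCC rho of 0.27, 0.22 and 0.30.

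**Figure D3:**
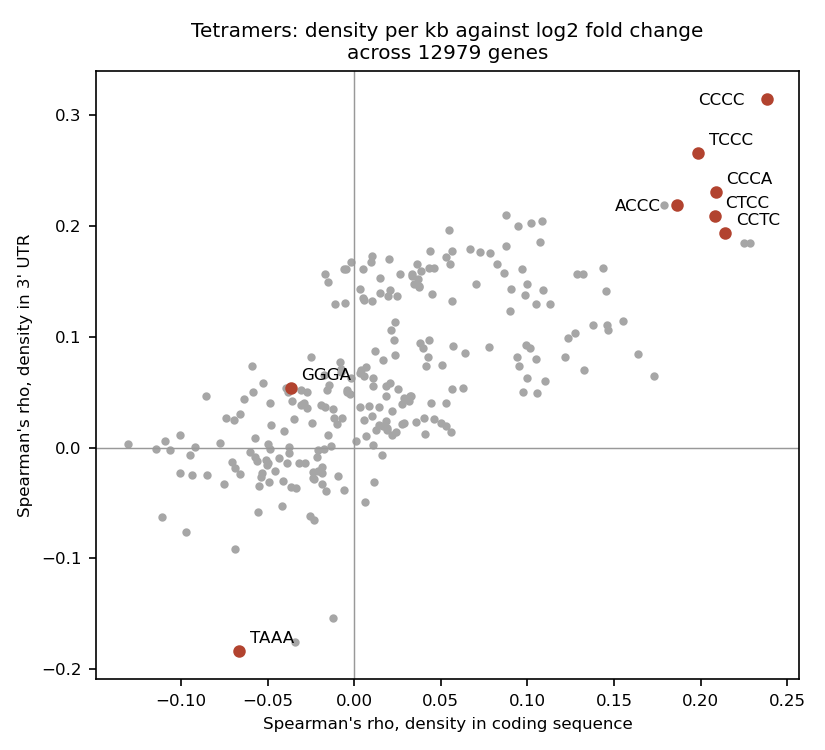
Spearman's rho of log2 fold change with the density per kb of each possible tetramer, in the coding sequence (x axis) and in the 3' UTR (y axis), across 12979 genes. CCCC and TCCC lie at the upper right, at 0.31 and 0.27 in the 3' UTR, and TAAA at the bottom, at −0.18.

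Length of the 3' UTR had a rho of 0.50 with log2 fold change across the same genes, above that of any tetramer. Coding length gave 0.26 and GC content of the 3' UTR 0.09. With genes divided into 10 equal bins, that of the shortest 3' UTRs (100 to 271 nt) had a median log2 fold change of −1.47 and that of the longest 1.08, where 49.5% of genes were enriched at least 2-fold and 3.70% depleted. From the lowest to the highest bin of TCCC density the median went from −1.28 to 0.47, and by CCCC density from −1.38 to 0.66. The 44 ribosomal protein and 65 oxidative phosphorylation genes with at least 100 nt of 3' UTR had medians of 456 and 246 nt, against 1249 nt over all such genes, and members with shorter 3' UTRs are left out of these medians.

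**Figure D4:**
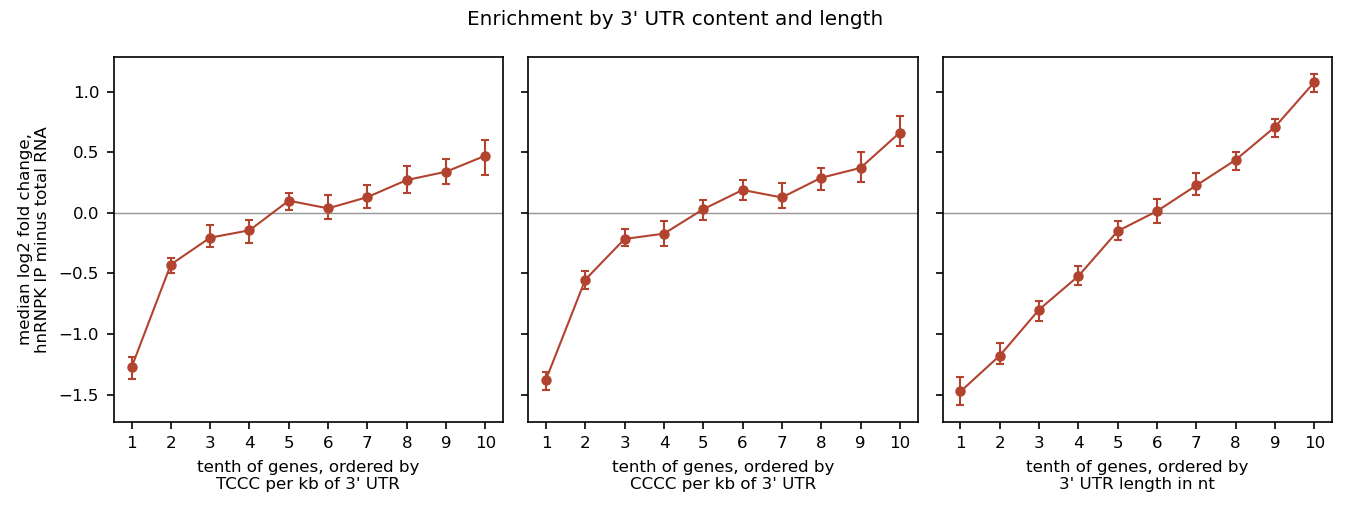
Median log2 fold change (hnRNPK IP minus total RNA) of genes divided into 10 bins by TCCC density, CCCC density and length of the 3' UTR, with 95% bootstrap intervals over genes. The medians run from −1.28 to 0.47 for TCCC, from −1.38 to 0.66 for CCCC and from −1.47 to 1.08 for length.

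Tetramers were counted with overlap, so a long run of C gives several CCCC. Jund's 3' UTR of 533 nt holds 4 TCCC and 22 CCCC. Its CCCC density lies at percentile 99.8 of all genes and its TCCC density at percentile 79.0. The 40 nt of it with the most CCCC and TCCC lie on chromosome 8 (GRCm38, 70700465 to 70700504, plus strand) and read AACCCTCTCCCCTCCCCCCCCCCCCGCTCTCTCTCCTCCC. Pdx1, with 5 TCCC and 8 CCCC in 1023 nt, has its densest 40 nt on chromosome 5 (147275247 to 147275286, plus strand), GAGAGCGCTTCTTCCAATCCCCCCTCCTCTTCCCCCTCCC. The TCCC and CCCC densities of Pdx1 lie at percentiles 55.8 and 79.7 of all genes. Gsk3a and Zfp385a were added for their C-rich 3' UTRs after their values were seen. The Gsk3a 3' UTR has 14 TCCC and 24 CCCC in 596 nt, with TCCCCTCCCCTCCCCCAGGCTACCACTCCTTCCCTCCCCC on chromosome 7 (25228553 to 25228592, minus strand). Zfp385a has 22 TCCC and 44 CCCC in 1100 nt, with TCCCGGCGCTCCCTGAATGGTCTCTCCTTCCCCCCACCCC on chromosome 15 (103314876 to 103314915, minus strand). Depleted genes could be C-rich as well, since Junb (−1.98 ± 0.19) has 13 CCCC in 485 nt, at percentile 98.8, and Uqcr11 (−5.21 ± 0.83) 3 in 189 nt, at percentile 94.7. Ddx3x has 2 of each in 2560 nt, Hnrnpk 2 TCCC and 4 CCCC in 1301 nt, and Ins2 2 TCCC and 1 CCCC in 298 nt. Counts per gene do not show where in a transcript hnRNPK was bound.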

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

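Halved counts were tried only after the even counts had been seen; the other alternatives were planned. The 3315 genes enriched at least 2-fold in the IP became 2039 with library totals alone, by construction of that scaling, which shifts the median of all genes by −0.43. The 5 lists called by camera became 8 with library totals alone and 8 with no filter, where the cause was not tested, 0 with an estimated correlation (lowest adjusted p = 0.422, 1 list at an unadjusted p under 0.05) and 18 with fry, which compares no list with other genes. The lists added by camera with library totals alone, and with no filter, were those of splicing factors, mitochondrially encoded genes and stromal markers. The median of matrix and adhesion genes turned from 0.67 to −0.11 with the gene length offset and to −0.22 with offset and block; the cause was not tested. Counts of enriched and depleted genes stayed within 1.5 times under the other alternatives. Leaving out 1 library gave 8956 to 11382 calls, against 10572, with none reversed. DESeq2 kept 10503 of them, limma-voom 10498, halved counts 10289 and the length offset 9071, with 117 reversed. Of 1896 values of 106 named genes when libraries, scaling, filter, tool or design were changed, 1859 kept direction and stayed called or not called as before, 21 lost the call, 1 gained it (Ndufb2 without IP replicate 2, 0.58) and 0 reversed a call. The remaining 15 turned in sign without being called, in Atp5g2 (6 values), Myc (3), Cd68, mt-Co3, Vim and Ndufb2. Those losing it were Ddx3x, Ins1, Hnrnpk, Rpl28, Casp6, Ppy and Col3a1, the last with offset and block (2.70). Among genes that kept their call, some fell in size, with lowest values of 0.84 for Igf1r, 0.71 for Sod2, 1.39 for Meg3 and 1.00 for Etv1. At an adjusted p under 0.01, 5 of the 97 named genes called were not called, Hnrnpk, Casp6, Rps4l, Rpl28 and Ppy; the 1.5-fold test was run on counts of genes. The TCCC correlation was 0.22 to 0.30 in all fits. With the replicate block 9748 genes were called, 9691 of them shared in direction and 0 reversed. The numbers showed no pairing of libraries, with same-numbered correlations of 0.000874, −0.0709 and 0.120, and not every library correlated best with its own number. With 3 libraries per group this check cannot exclude that libraries of the same number shared a lysate. Of all single gene and list values, 2247 stayed called or not called as before, 36 gained a call, 30 lost it and 2 reversed. Of these 2247, the 15 gene values above and 27 values of 7 lists turned in sign or in the direction of the list test, none of them called. Histones gained their call with the length offset, alone and with the block, in the direction opposite to that without it. Among 2740 genes with 10 to 40 counts on average in total RNA, IP library 3 lacked a read for 291 and total RNA library 3, of similar depth, for 6, although the choice by total RNA favours the latter.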

Other observations

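The gene families by symbol prefix and the tests on ribosomal protein and oxidative phosphorylation mRNAs and on mitochondrial rRNA, and the TMM scaling of receptor and pseudogene sums, were chosen after the results were seen; the tests on mitochondrial C-rich sequence, on genomic DNA, on host mRNAs and on other splits were planned. Mitochondrial ribosomal protein genes (prefix Mrp) had 3 enriched and 67 depleted of 77, with a median log2 fold change of −2.56 (camera, Benjamini-Hochberg adjusted p = 2.99e-09 over 143 families; adjusted p = 0.460 with an estimated correlation). Among them Mrps12 lay at −4.15 ± 0.20 with 2.50 CPM in the IP and 44.4 in total RNA. Its enriched members were Mrps2 (1.72 ± 0.12), Mrpl1 (1.38 ± 0.16) and Mrpl10 (0.71 ± 0.12). Proteasome genes (Psm) had 3 enriched and 45 depleted of 48 and a median of −2.62 (camera, Benjamini-Hochberg adjusted p = 1.53e-08; adjusted p = 0.425 with an estimated correlation). The core subunit Psma6 was depleted (−4.30 ± 0.43), and the enriched members were the activator Psme3 (2.00 ± 0.10), Psmd11 (1.55 ± 0.15) and the inhibitor Psmf1 (0.80 ± 0.11). Polymerase genes (Pol) had 4 enriched and 35 depleted of 51, with Polr2a, the RNA polymerase II subunit that carries the C-terminal repeats, at 3.16 ± 0.08 and the small subunit Polr2f at −3.97 ± 0.26. Camera gave the polymerase family a Benjamini-Hochberg adjusted p = 0.000624 (adjusted p = 0.420 with an estimated correlation).

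Protocadherin genes (Pcd) had 34 enriched and 1 depleted of 54 and a median of 1.04, with Pcdhgb7 at 2.37 ± 0.23, although clustered protocadherins share exons and their reads cannot be divided with certainty. The depleted member was Pcdh20 (−1.29 ± 0.47). Forkhead genes (Fox) had 19 enriched and 3 depleted of 24 and a median of 1.60. Foxp4 had 871 CPM in the IP and 146 in total RNA, whereas Foxa2, a factor of pancreatic development, was depleted (−0.72 ± 0.09), as were Foxa3 (−1.88 ± 0.15) and Foxred1 (−1.15 ± 0.23), which is no forkhead factor. Camera gave Benjamini-Hochberg adjusted p = 0.000137 for protocadherins and 0.000810 for the Fox prefix (adjusted p = 0.425 and 0.420 with an estimated correlation). Potassium channel genes (Kcn) had 30 enriched and 8 depleted of 59, among them Kcnj6 (2.48 ± 0.14), and a median of 0.87 (camera, Benjamini-Hochberg adjusted p = 0.00733; adjusted p = 0.420 with an estimated correlation). Among gene classes, antisense transcripts had 122 enriched and 30 depleted of 587, lincRNAs 119 and 40 of 530, processed pseudogenes 158 and 552 of 1095 and snoRNA genes 4 and 18 of 54.

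The 161 protein-coding ribosomal protein and oxidative phosphorylation members had a median log2 fold change of −3.78 and short mRNAs, with a median of 835 nt. Against the 20 genes nearest in mRNA length their median difference was −1.948 (95% interval −2.071 to −1.43). A regression on lengths, GC content and C-rich densities of 3' UTR and coding sequence left a median residual of −1.659 (−1.859 to −1.502). It explained 38.7% of the variance among the other genes. Lengths came from the transcript with the longest annotated 3' UTR, which may not be the one expressed. Annotated length and these densities thus left part of the depletion, and the length of the expressed mRNAs was not measured. Adding 295 pseudogenes named after ribosomal protein genes left a log2 ratio of −4.187 between IP and total RNA scaled by library totals, ranging from −4.767 to −3.53 over pairs of libraries, and −3.76 with TMM factors. This argues against reads moved to these pseudogenes. Reads given to pseudogenes under other names, or dropped, are not covered by that sum. Genes matched for length were depleted too, with a median of −1.93, so length may carry part of the pattern. A low affinity of hnRNPK for these mRNAs, their place in polysomes and a loss of short RNA in the IP protocol beyond the trend with length stay open and were not tested, nor was binding to beads without the antibody.

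The 7 mitochondrially encoded mRNAs with at least 5 CPM had a median log2 fold change of 2.51. Mitochondrial rRNAs did not follow, with mt-Rnr1 at −3.06 ± 0.10 and mt-Rnr2 at 0.14 ± 0.10, and their mean lay −3.975 from the mRNA median, which argues against carry-over of whole mitochondria as the only source. A removal of rRNA that differed between the groups could also lower them, and the tRNA mt-Tp at 1.95 ± 0.26 goes with carry-over, but the mRNAs differed from each other as well, from mt-Co1 at 1.00 ± 0.18 to mt-Nd6 at 2.77 ± 0.24. C-rich sequence gave no decision, with a Spearman's rho of −0.2143 across 7 genes (exact permutation test, p = 0.662). Binding by hnRNPK inside or outside mitochondria stays open and was not tested.

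Sense intronic transcripts had 21 enriched and 0 depleted of 53 by edgeR (2 depleted at an unadjusted p under 0.05, 1 with DESeq2 and 2 with limma-voom), with a median log2 fold change of 1.15. Genes of the TEC class, loci still to be checked by experiment, had 135 and 15 of 498 (median 0.99). Over all genes tested, 28.9% were enriched and 33.6% depleted. Genomic DNA would raise silent genes as well. Over 1728 olfactory and vomeronasal receptor genes the IP to total RNA ratio was 1.067 scaled by library totals but 1.44 with TMM factors. The latter lies between the planned bounds, which had named no scaling, so the ratio gave no decision. Reads fell on 23, 15 and 50 of these genes in IP libraries 1, 2 and 3, and on 52, 54 and 60 in the total RNA libraries. Genomic DNA would spread reads over many of them, so these counts, not part of the planned test, argue against it as the main source. IP libraries detected fewer genes in general, so a small share of genomic DNA stays open. The 286 of these transcripts inside a single tested gene exceeded their host by a median of 0.9876 (95% interval 0.715 to 1.246), with 208 above it. That passed the planned bound against enrichment of the host's spliced mRNA alone. Transcripts with few reads in total RNA could pass the filter only through their IP counts, however, which fixes their direction. How many did so was not counted, so the comparison does not settle the question. A candidate explanation that stays open is binding of hnRNPK, a largely nuclear protein, to unspliced RNA, and without a known strand setting overlapping antisense RNA stays open too.

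The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. As many genes or lists as in the real split came from 1 of the 10 splits, the real one, for each count. The real split gave 4892 enriched and 5680 depleted genes, 3315 and 4148 of them at least 2-fold, and the highest of the others gave 0 by edgeR for each, with 26 to 119 genes at an unadjusted p under 0.05 against 11164. Every other split mixes IP and total RNA libraries within both groups. The difference between them then adds to the spread, so few genes could be called there by design. Camera called 5 lists in the real split and at most 4 in another.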
